A study of Mus musculus with 9 samples.

How the data were processed

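Values of 9 Affymetrix whole-transcript arrays were used, 3 for each of 3 groups of MA-10 cells: DMSO control, 10 µM forskolin, and 10 µM forskolin with 1 mM AICAR, all for 1.5 h. The titles of the control samples speak of no treatment while their treatment field names DMSO, and they were taken as DMSO controls. The deposited values are log2 summaries per transcript cluster (called probe here), which the submitters' processing notes credit to RMA and Partek, without versions or settings. In its usual form RMA corrects the background, makes the arrays share 1 distribution and takes a median polish over the probes of a cluster. The array medians lay within 0.1 of each other, no value was missing, and no array duplicated another. Per the labels the RNA of the replicates was not pooled.

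The table held 35557 probes, of which 21789 carried 1 gene symbol, 1621 several and 12147 none listed. Only probes with 1 symbol were used, and for 998 genes with more than 1 probe the one with the highest mean over all arrays, which left 19938 genes. Symbols were checked through their Entrez identifiers against a RefSeq gene table of the mouse assembly GRCm38.p6. That table was otherwise used only to match older symbols of gene list members and to find the microRNA genes lying between Meg3 and Mirg. No positions are given because the files name no genome build. There was no filter on dim probes. The number of arrays limits the precision.

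The 3 comparisons were forskolin against control, forskolin with AICAR against forskolin, and forskolin with AICAR against control. All 9 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with its moderated test, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called changed at an adjusted p under 0.05, and the number that also changed at least 1.5-fold was counted. Log2 differences are given with their standard error. Of genes raised by forskolin and lowered by AICAR, the count was set beside the overlap of independent lists and beside simulated data sets without effects, made by recombining the residuals of the fit. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

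The tests with limma, camera and fry, the 27 gene lists, the rule for naming genes and all alternatives except 3 were chosen before the data were examined. The gene classes with their tests, the tests of the array axis and of the intensity trend, and the further simulations were chosen afterwards. The lists were immediate early genes, cAMP and CREB targets, cAMP signalling and feedback, MAPK phosphatases and Sprouty genes, steroidogenesis, transcription factors of steroidogenic cells, cholesterol biosynthesis, lipogenesis, fatty acid oxidation and mitochondrial biogenesis, AMPK components, purine and adenosine metabolism, p53 targets, the integrated stress response, the unfolded protein response, heat shock proteins, glycolysis and hypoxia, FOXO and MondoA targets, the circadian clock, growth factors with cytokines and NF-kappaB targets, YAP and SRF targets, TGF-beta with BMP and activin genes, the cell cycle, and markers of Sertoli, germ, macrophage, peritubular and fibroblast, and endothelial cells. Members recur between lists, so the lists are not independent. Each was tested as a set with camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests whether its members move one way on balance.

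The genes named were the 8 largest rises and 8 largest falls per comparison among called genes whose replicates did not overlap between the groups, up to 4 called members per list with the largest change (or, with none called, the member with the smallest p), and 10 genes named in advance: Star, Cyp11a1, Cyp17a1, Hsd3b1, Nr5a1, Nr4a1, Nr0b1, Jun, Fos and Crem. To these came the 8 with the largest AICAR change in each direction among genes raised by forskolin and lowered by AICAR and among genes called only with AICAR. Unnamed and predicted transcripts, olfactory and vomeronasal receptors and replication-dependent histones were counted but not named. Other called list members are mentioned to complete counts, and a few genes chosen after their values were seen are marked.

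Alternatives were a replicate block, filters at a mean log2 value of at least 5 or 6, quantile normalization or median centring of the deposited values, a trended and robust prior, no moderation, fits of only 2 groups, array weights, every probe or the mean of a gene's probes, other thresholds, and each array left out in turn. Added after the data were seen were the first component of the within-group deviations as a covariate (the array axis, its scores shifted between groups by an amount estimated across genes by robust regression of the group differences on the loadings), the removal of each array's intensity trend by a lowess curve of span 0.3, and the omission of replicate 3 of every group. The procedure was tested on simulated data with known changes and noise drawn independently for each gene. In each comparison 76% of 1.25-fold changes and 100% of changes of 1.5-fold or more were recovered. Of all calls 4.57%, 6% and 5.53% were false in the 3 comparisons. In data with a simulated axis, 2.11% of calls were false without the axis as a covariate and 6.57% with it.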

Results

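MA-10 cells, a mouse Leydig tumour cell line that makes steroids when cAMP rises, were profiled on 9 Affymetrix whole-transcript arrays. For 1.5 h in serum-free medium the cells received the DMSO vehicle (3 arrays, called control below), 10 µM forskolin (3 arrays) or 10 µM forskolin with 1 mM AICAR (3 arrays). Forskolin activates adenylyl cyclase and so raises cAMP. AICAR is taken up and phosphorylated to ZMP, an AMP mimic that activates the energy sensor AMPK. The design asks how the cells' transcripts responded to forskolin and how AICAR altered that response. Cells given AICAR without forskolin were not analysed here, so the AICAR comparison is between cells that all received forskolin. The array medians lay between log2 values of 7.14 and 7.19, and the interquartile ranges between 3.34 and 3.48. The narrowest ranges were those of AICAR replicates 2 and 3 (3.349 and 3.341), against 3.416 to 3.482 in the other arrays. The number of arrays limits the precision. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples.

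Forskolin raised Star, which encodes the protein that moves cholesterol into mitochondria for steroid synthesis, 3.7-fold. Its log2 value went from 8.58 ± 0.03 in control to 10.47 ± 0.12 with forskolin (SD, n = 3; log2 difference 1.89, SE 0.06, adjusted p = 2.8e-07). The nuclear receptors Nr4a1 and Nr4a3 rose 6.22-fold and 5.07-fold (log2 differences 2.64, SE 0.05, and 2.34, SE 0.07), and the cAMP-induced kinase Sik1 rose 6.04-fold (2.60, SE 0.07). Plau, the urokinase plasminogen activator, rose 3.39-fold, Rasgef1b 2.57-fold, Fosb 2.22-fold and Klf4 2.11-fold. Txnip, a thioredoxin-binding protein that restrains glucose uptake, fell 5.01-fold (log2 difference −2.33, SE 0.14, adjusted p = 3.8e-05). The next deepest falls were smaller, at log2 differences of −0.59 for Cdc42ep3, −0.48 for Nr0b2 and Ifitm7, −0.47 for Inhba, −0.42 for Strip2 and Hpdl, and −0.41 for Klf10. Of 19938 genes tested, 138 changed at an adjusted p under 0.05, 99 higher and 39 lower (71.7% higher, against 48.6% of 436 genes with array weights), and 33 of them changed at least 1.5-fold, 31 higher and 2 lower (Txnip and Cdc42ep3). The 2 groups did not overlap in 14% of genes, against 10% by chance. The enzymes after Star in the pathway did not pass the test, with log2 differences of 0.12 for Cyp11a1 (adjusted p = 0.51), 0.29 for Cyp17a1 (adjusted p = 0.42) and 0.21 for Hsd3b1 (adjusted p = 0.85). Neither did the transcription factor genes Nr5a1 (−0.11, adjusted p = 0.41), Nr0b1 (−0.04, adjusted p = 0.94) and Crem (0.15, adjusted p = 0.38). Leaving out any 1 of the 6 control and forskolin arrays lowered the number of changed genes to between 76 and 91. That ended the call of Strip2 (without any of these arrays but forskolin replicate 3) and of Klf10 (without any but control replicate 1), each with an adjusted p of up to 0.11.

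**Figure D1:**
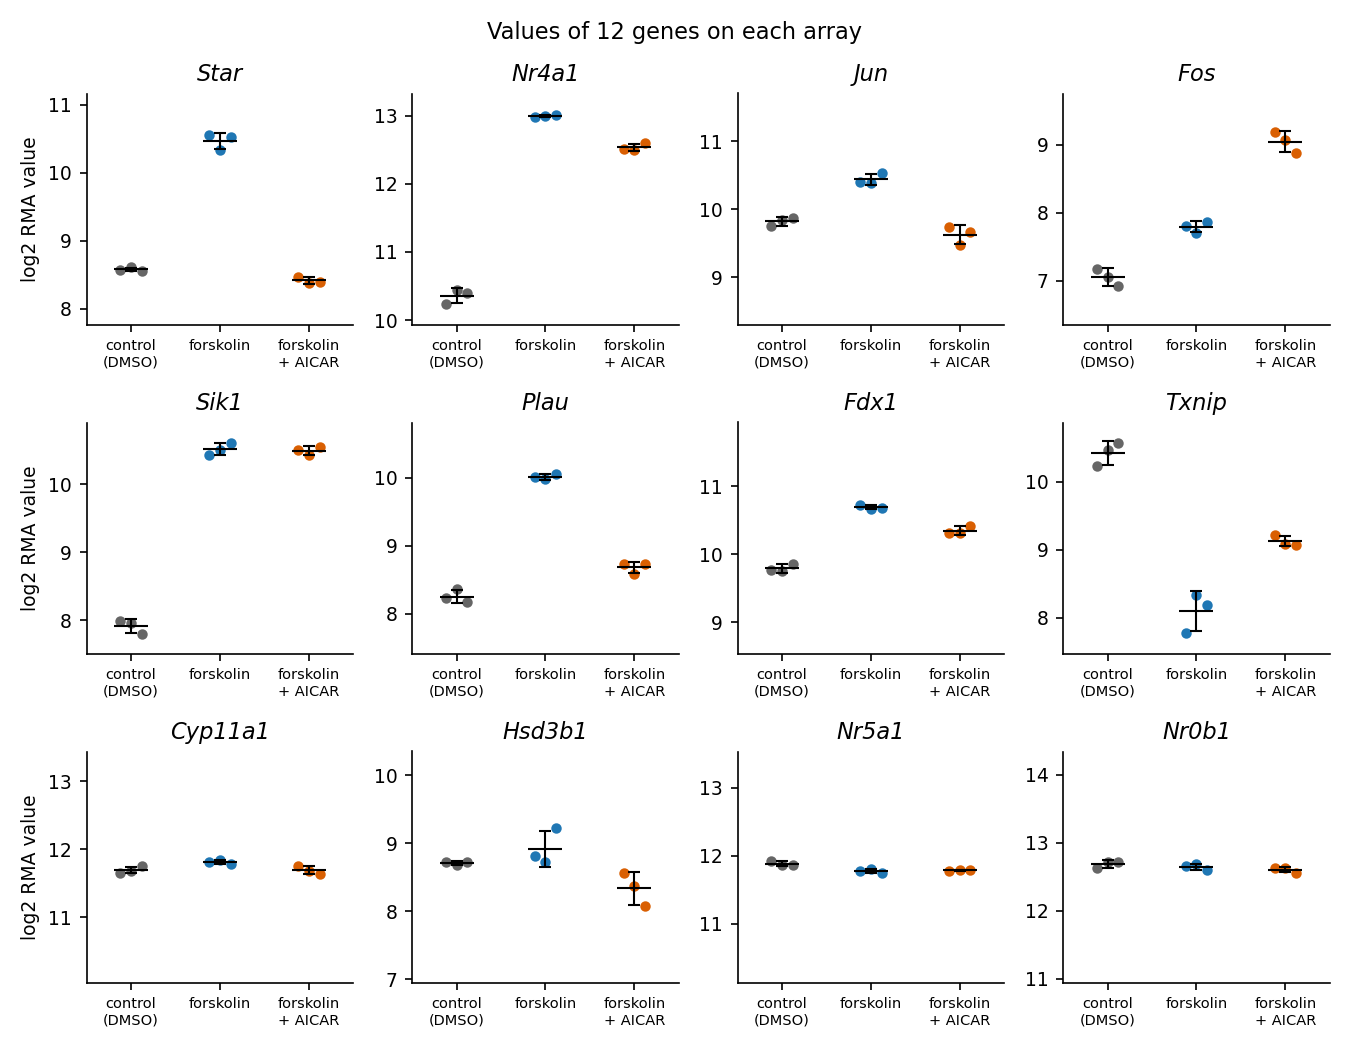
Log2 RMA value (vertical axis, each panel spanning the same range) of 12 genes on each of the 9 arrays. Points are arrays, horizontal bars group means and whiskers 1 SD (n = 3). Star rose from 8.58 to 10.47 with forskolin and stood at 8.42 with forskolin and AICAR, whereas Fos was highest with both compounds, at 9.05.

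The gene lists with the most members called after forskolin were immediate early genes and cAMP targets. Of 32 measured immediate early genes, 12 rose, among them Fosb (1.15), Klf4 (1.08), Fos (0.74), Jun (0.61) and Junb (0.59), Klf10 fell and 19 did not pass the test (19 higher and 3 lower when adjusted over the list alone). Of 29 cAMP and CREB target genes, 9 rose, Inhba fell and 19 did not pass (13 and 1 adjusted over the list alone). This list shares Nr4a1, Nr4a3, Fos and Fosb with the immediate early list and also held rises of Sik1, Per1, Bhlhe40 and Dusp1. In the steroidogenesis list, Star, the electron donor Fdx1 (0.90, SE 0.05) and the lipoprotein receptor Scarb1 (0.35, SE 0.05) rose and 16 of 19 members did not pass (9 higher and 0 lower adjusted over the list alone). These 3 lists were higher as sets in camera, and their calls held with an estimated correlation between genes (adjusted p = 0.021, 0.031 and 0.049). Of 17 MAPK phosphatase and Sprouty genes, which damp MAP kinase signalling, Dusp16 (0.90), Dusp1 (0.64), Dusp5 (0.58) and Dusp4 (0.53) rose (4 and 0 adjusted over the list alone), and the set was called higher but not with an estimated correlation (adjusted p = 0.13). Among 32 transcription factors of steroidogenic cells, Jun, Junb, Fos, Nr4a1 and Nr4a3 rose and Nr0b2 fell (7 and 3 adjusted over the list alone; set adjusted p = 0.012, and adjusted p = 0.2 with an estimated correlation).

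Smaller groups of other lists moved with forskolin. Of 18 circadian clock genes, Bhlhe40 (0.90), Per1 (0.84), Per2 (0.41) and Csnk1e rose and Nr1d1 (−0.30) fell (6 and 1 adjusted over the list alone). That set was called higher (adjusted p = 0.036) although its median was −0.02 and its mean 0.13, and not with an estimated correlation (adjusted p = 0.65). It also lost its call without control replicate 1 (adjusted p = 0.12), forskolin replicate 3 (0.13) or any 1 AICAR array (0.057 to 0.095). Of 22 FOXO and MondoA targets, G6pc (0.63), Arrdc3 (0.60) and Bcl2l11 (0.43) rose and Txnip fell (5 and 2 adjusted over the list alone), and this set, not called, had a median of 0.01 and a mean of −0.02. Plk3 (0.97) and Btg2 (0.39) rose among 22 p53 targets (2 and 0 adjusted over the list alone), and Smad7 (0.30) rose and Inhba fell among 23 TGF-beta, BMP and activin genes (5 and 1 adjusted over the list alone). Single members rose in 5 lists, namely Sik1 of 38 cAMP signalling and feedback genes, Ddit4 (0.32) of 24 integrated stress response genes, Hspa1a (0.72) of 16 heat shock genes, Hk2 (0.23) of 24 glycolysis and hypoxia genes and Amotl2 (0.84) of 24 YAP and SRF targets. Adjusted over the list alone, these 5 lists had 1, 3, 1, 2 and 1 members higher and 0 lower. In 13 lists limma called no member, with 20 of their 247 genes at an unadjusted p under 0.05. They covered cholesterol biosynthesis, lipogenesis, fatty acid oxidation, AMPK components, purine metabolism, the unfolded protein response, cytokines and NF-kappaB targets, the cell cycle, and markers of Sertoli, germ, macrophage, peritubular and endothelial cells. The nearest to a call were Tbc1d4 (−0.20, adjusted p = 0.093) and Aurka (−0.28, adjusted p = 0.096), and 1 AMPK and 1 cell cycle gene were lower when adjusted over the list alone. In all, camera called 11 of 27 lists, and the p53, integrated stress, TGF-beta, cholesterol and cell cycle calls were lost with an estimated correlation (adjusted p = 0.33 for all but integrated stress, 0.46). Cholesterol and cell cycle genes were lower as sets and the others higher, and the integrated stress call was also lost without forskolin replicate 3 (adjusted p = 0.081). Dusp4 lost its call without control replicate 1 or 3 (adjusted p up to 0.06). Ddit4, Hk2, Per2, Nr1d1 and Smad7 lost theirs without any of at least 5 single arrays, control replicate 3 among them for each, at adjusted p of up to 0.083, 0.19, 0.12, 0.11 and 0.18.

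AICAR added to forskolin brought Star down 4.14-fold from its forskolin level, to a log2 value of 8.42 ± 0.05 against 10.47 ± 0.12 (SD, n = 3; log2 difference −2.05, SE 0.06, adjusted p = 5.2e-07). Plau and the microRNA gene Mir379 fell 2.51-fold, and Mir380, Mir127, Gdpgp1, Kbtbd8 and Zfp719 fell 2.4-fold, 2.38-fold, 2.3-fold, 2.21-fold and 2.06-fold. Jun fell 1.76-fold (−0.81, SE 0.07, adjusted p = 0.00037) whereas Fos rose 2.38-fold (1.25, SE 0.09, adjusted p = 0.0001), so that these AP-1 partners moved apart. Txnip rose 2.03-fold (1.02, SE 0.14, adjusted p = 0.0026), Mir99a 1.92-fold and Epo, which encodes erythropoietin, 1.56-fold. In all 1017 genes changed, 195 higher and 822 lower, and 132 changed at least 1.5-fold, 4 higher (Fos, Txnip, Mir99a and Epo) and 128 lower. Of the changed genes 19.2% were higher, whereas after quantile normalization of the deposited values 389 were higher and 766 lower, or 33.7% higher. The excess of falls was absent without AICAR replicate 1 (1677 higher and 1647 lower) and with array weights (3075 higher and 2654 lower). The groups did not overlap in 23.6% of genes, against 10% by chance.

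Among genes that forskolin alone left uncalled, AICAR lowered 743 and raised 186. The notch ligand Dll1 (−0.97, SE 0.05) and Mir329 (−0.99, SE 0.16) were among those lowered, and the FOXO target Ccng2 (0.55), Mirlet7d (0.52), the vasodilator peptide gene Adm (0.50) and Kank3 (0.48) among those raised. Mir99ahg, the host of Mir99a, was called higher through its brightest probe (0.55), but 2 of its other probes were lower (−0.76 and −0.36) and the mean of its probes gave −0.11. The steroidogenic genes Cyp11a1 (−0.12, adjusted p = 0.14) and Cyp17a1 (−0.34, adjusted p = 0.08) did not pass the test, nor did Nr5a1 (0.01, adjusted p = 0.87), Nr0b1 (−0.05, adjusted p = 0.47) and Crem (−0.09, adjusted p = 0.27). The count of changed genes rested on the arrays used. Without forskolin replicate 1, 2 or 3 it was 643, 575 or 487, without AICAR replicate 2 it was 528, and without AICAR replicate 1 it was 3324. Epo lost its call without AICAR replicate 2 (adjusted p = 0.053), Kank3 without forskolin replicate 1 or 3 (up to 0.054) and Mirlet7d without any 1 forskolin array or AICAR replicate 2 (up to 0.088).

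The arrays also differed in a way the groups do not name. The first component of the deviations from the group means held 46.04% of their sum of squares, and it set AICAR replicate 1 (−0.60) apart from AICAR replicate 3 (0.56) and, more weakly, control and forskolin replicate 3 (−0.31 and −0.34) from their groups. Across genes, the AICAR change correlated with the deviation of control replicate 3 from the other controls at r = −0.37, where genes are not independent replicates. Deviations from group means cannot show whether the groups also differ on this axis, so before its use as a covariate the scores of each treated group were shifted by an amount estimated across genes by robust regression of its difference from control on the gene loadings. This put the AICAR arrays at 0.07, 0.70 and 1.22 and the forskolin arrays at 0.30, 0.18 and −0.26, and it takes the part of the group difference that follows the loadings as belonging to the axis. With this shifted array axis as a covariate, 658 genes changed with AICAR, 134 higher and 524 lower, and 549 of them were among the 1017. Without replicate 3 of every group, 241 changed, 20 higher and 221 lower.

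**Figure D2:**
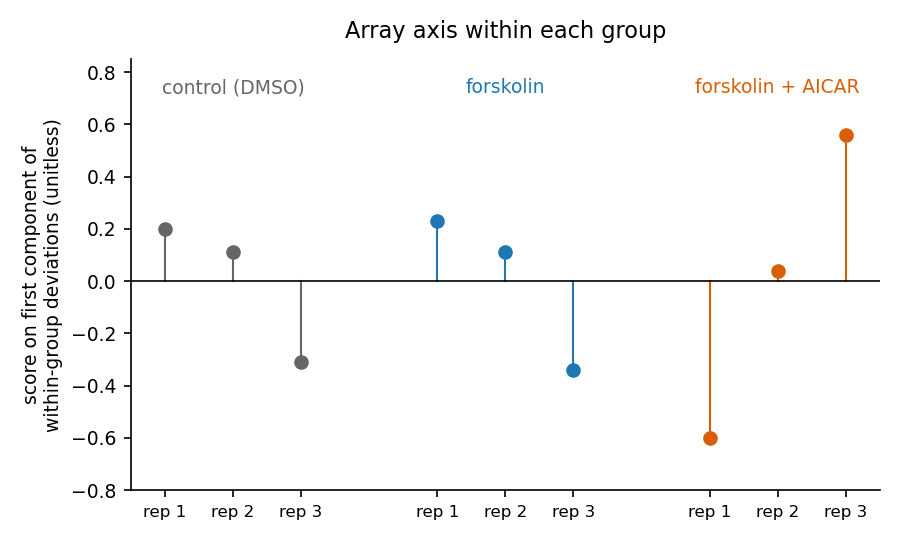
Score of each array (vertical axis, unitless) on the first component of the deviations from the group means, for the 3 replicates of each group, without the shift between groups that the covariate includes, so that the scores of each group average 0. The AICAR arrays span −0.60 to 0.56, and the control and forskolin arrays −0.34 to 0.23.

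Several lists that forskolin had raised were lower with AICAR. In the steroidogenesis list 6 of 19 members fell, Star, Hsd3b1 (−0.59, SE 0.14, adjusted p = 0.044), Hsd3b6, Scarb1 (−0.35, SE 0.05), Fdx1 (−0.34, SE 0.05) and Lipe, and the cholesterol carrier Stard4 (0.19) rose (1 higher and 8 lower adjusted over the list alone). The set was lower in camera (adjusted p = 3.2e-05), and not called with an estimated correlation (adjusted p = 0.45). Of 32 immediate early genes, 8 fell, with Nr4a3 (−1.02), Jun and Klf4 (−0.79) furthest, while Fos, Egr1 (0.40) and Junb (0.23) rose and 21 did not pass (4 and 13 adjusted over the list alone). Of 29 cAMP and CREB targets, Dusp1 (−0.83), Gadd45b (−0.62), Nr4a1 (−0.46), Nr4a3, Cited2 and Cebpb fell and Fos and Nfil3 rose (3 and 9 adjusted over the list alone). Dusp1, the EGF receptor inhibitor Errfi1 (−0.57), Dusp5 (−0.29) and Dusp16 (−0.25) fell among 17 MAPK phosphatase and Sprouty genes (2 and 7 adjusted over the list alone). These 3 sets were lower in camera (adjusted p = 0.0022, 0.02 and 0.0029), and none with an estimated correlation (adjusted p = 0.45, 0.49 and 0.45). The cAMP target set also lost its call without AICAR replicate 1 (adjusted p = 0.085). Without forskolin replicate 3 or AICAR replicate 2, Dusp5 and Dusp16 were not called (adjusted p up to 0.054 for each). Hsd3b1 lost its call without any 1 array but forskolin replicate 2 and AICAR replicate 1 (adjusted p up to 0.12). Of 32 transcription factors of steroidogenic cells, Fos, Junb and Mef2c rose and Jun, Nr4a1, Nr4a3, Nr0b2 and Cebpb fell (4 and 5 adjusted over the list alone). Prkar2b (−0.35) fell alone among 38 cAMP signalling and feedback genes (0 and 1 adjusted over the list alone), not without forskolin replicate 1 or 3 or AICAR replicate 2 (adjusted p up to 0.064).

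Of 24 glycolysis and hypoxia genes, 5 were called higher, 1 lower and 18 neither: Ankrd37 (0.47, SE 0.06), Adm, Pfkl (0.33), the angiogenic factor Vegfa (0.28, SE 0.04) and Pgk1 rose, and Pfkfb3 (−0.49, SE 0.05), which makes an activator of glycolysis, fell (12 and 2 adjusted over the list alone). The set was higher in camera (adjusted p = 0.0008) and not with an estimated correlation (adjusted p = 0.45). Some members of stress lists fell, and the calls of these lists as sets were not kept with an estimated correlation. In the integrated stress response, Ddit3 (−0.53), the cystine transporter Slc7a11 (−0.53), Cebpb (−0.24) and Nupr1 (−0.22) fell among 24 (0 and 9 adjusted over the list alone). Plk3 (−0.72), Btg2 (−0.51), Trp53inp1 (−0.38) and Gadd45a (−0.31) fell among 22 p53 targets (1 and 5), Hspa1a (−0.57) and Dnajb1 (−0.22) among 16 heat shock genes (0 and 2), and Xbp1 (−0.28) and Edem1 (−0.19) among 17 genes of the unfolded protein response (0 and 3, all adjusted over the list alone). These 4 sets were lower in camera (adjusted p = 0.0008, 0.027, 0.0022 and 0.013), each with adjusted p = 0.45 with an estimated correlation. The p53 set lost its call without forskolin replicate 1 (adjusted p = 0.062) or AICAR replicate 2 (0.084), and the unfolded protein set without AICAR replicate 2 (0.077). With the array axis as a covariate the p53, heat shock and unfolded protein sets were not called. Slc7a11 lost its call without forskolin replicate 3 (adjusted p = 0.06). Of 22 FOXO and MondoA targets, Bcl6 (−0.83), G6pc (−0.80), Cited2, Fbxo32, Bcl2l11 and Gadd45a fell while Txnip, Ccng2 and Klf11 rose (3 and 7 adjusted over the list alone), and the set was not called. Per2 (−0.47), Cry2 (−0.24) and Csnk1e (−0.16) fell and Nfil3 (0.30) rose among 18 clock genes (3 and 5 adjusted over the list alone).

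Of metabolic genes, the catalytic AMPK subunit Prkaa1 (−0.24) and the regulatory subunit Prkag3 (−0.23) fell among 20 AMPK components (0 and 2 adjusted over the list alone). Ppara (−0.23) and Cpt1a (−0.17) fell among 21 genes of fatty acid oxidation (1 and 2), Elovl6 (−0.16) among 18 of lipogenesis (2 and 1), and Insig1 (−0.19) fell while Stard4 rose among 22 of cholesterol biosynthesis (1 and 1, all adjusted over the list alone). Prps1 (−0.29), which makes the precursor of purine synthesis, fell among 23 purine genes (0 and 3 adjusted over the list alone), a set called lower (adjusted p = 0.018) but not with an estimated correlation (adjusted p = 0.45), with the array axis as a covariate or without AICAR replicate 3 (adjusted p = 0.056). Tgif1 (−0.41) and Id1 (−0.36) fell among 23 TGF-beta, BMP and activin genes (2 and 4), and Vegfa rose among 27 growth factor, cytokine and NF-kappaB genes (2 and 1, both adjusted over the list alone). Sox9 (−0.46) fell among 14 Sertoli cell markers (0 and 2 adjusted over the list alone), where the median was 0.05 and fry put the set lower without a call, and Cd68 (−0.39) among 15 macrophage markers (0 and 1 adjusted over the list alone), where the median was 0.10 and, after quantile normalization, 0.03. The 15 peritubular and fibroblast markers had a median of 0.19 (0.11 after quantile normalization) and were called higher as a set (adjusted p = 0.0022), but not with an estimated correlation (adjusted p = 0.47) or with the array axis as a covariate. In that list and in the YAP and SRF, cell cycle, germ cell and endothelial lists limma called no member, Ccne1 (−0.17, adjusted p = 0.057) and Pdgfrb (0.19, adjusted p = 0.074) coming nearest. Of the 91 genes of these 5 lists 25 had an unadjusted p under 0.05, and adjusted over the list alone 2 cell cycle genes were higher and 3 lower and 0 genes of the other 4 lists changed. Camera called 11 lists in all, 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 12. Of the 68 called genes named for the AICAR comparison, 23 lost their call with at least 1 array left out, among them, each without forskolin replicate 2 or 3 as well as other arrays, Stard4 (adjusted p up to 0.14), Prkaa1 (0.12), Prkag3 (0.085), Ppara (0.057), Cpt1a (0.089), Elovl6 (0.093), Prps1 (0.12), Pfkl (0.069), Nfil3 (0.097), Id1 (0.1), Cry2 (0.15), Csnk1e (0.12), Nupr1 (0.11), Dnajb1 (0.073) and Edem1 (0.16). With the array axis as a covariate 18 lost it.

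**Figure D3:**
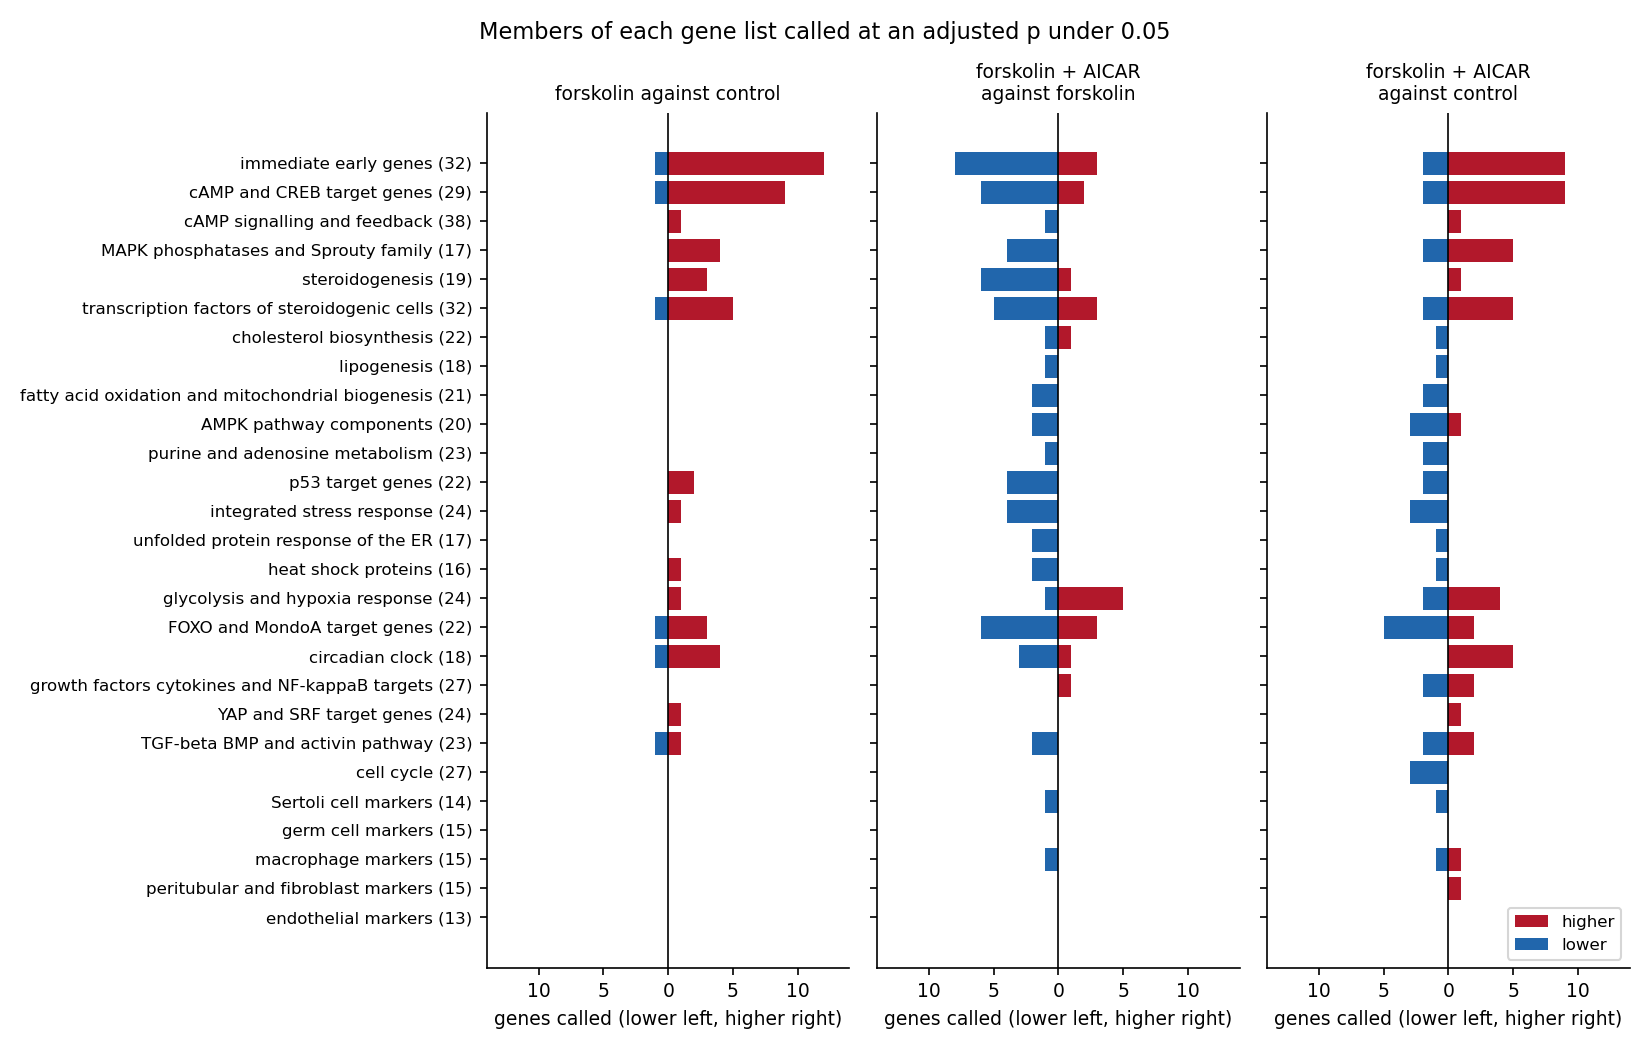
Number of genes called at an adjusted p under 0.05 (horizontal axis, lower to the left and higher to the right) in each of the 27 gene lists, with the number measured in brackets, for the 3 comparisons. Immediate early genes show 12 higher and 1 lower with forskolin, and 3 higher and 8 lower when AICAR is added.

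Many genes that forskolin raised were lower when AICAR was given with it. Of the 99 genes that forskolin raised, 72 were lower with AICAR than with forskolin alone, 3 (Fos, Egr1 and Junb) were higher and 24 were not called. With AICAR, 12 of the 72 still exceeded control, 51 did not differ detectably from it and 9 were below it. Star was among those not called against control (log2 difference −0.16, SE 0.06, adjusted p = 0.11). The largest falls among the 72 were in Star, the unnamed transcript BC023105 (−1.60, named here after its value was seen), Plau, Ttll10 (−1.04), Nr4a3 (−1.02), Ccnjl (−0.84), Dusp1 (−0.83) and Jun (−0.81). The 31 genes raised at least 1.5-fold had a median log2 rise of 0.84 with forskolin, and the median of their changes with AICAR was −0.46 (−0.48, −0.49 and −0.43 in the 3 AICAR arrays). Of these 31, 21 fell, Fos and Junb rose, and 8 were not called, among them Sik1 (−0.02, adjusted p = 0.86). Of 39 genes that forskolin lowered, AICAR raised 6, among them Txnip, and lowered 7, among them Nr0b2.

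Both comparisons use the same forskolin arrays, which by itself makes their changes oppose. Lists of these sizes drawn independently would share 4.08 genes higher with forskolin and lower with AICAR, against 72. In 100 simulated data sets with no effect, 99 had 0 such genes and 1 had 2585. These data sets held no forskolin effect either, so they cannot show how many genes raised by forskolin would fall back by chance. Across genes the covariance of the log2 changes was −0.0024, against a simulated mean of −0.0026. When the genes were picked with 2 forskolin arrays and the AICAR change was taken from the forskolin array left out, the median was −0.38, −0.46 and −0.58. The 3 forskolin arrays cannot be split into parts of 2 each, so the share of the 72 that the shared arrays account for was not separated. The count of 72 became 44, 47 and 45 without control replicate 1, control replicate 3 and forskolin replicate 3.

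**Figure D4:**
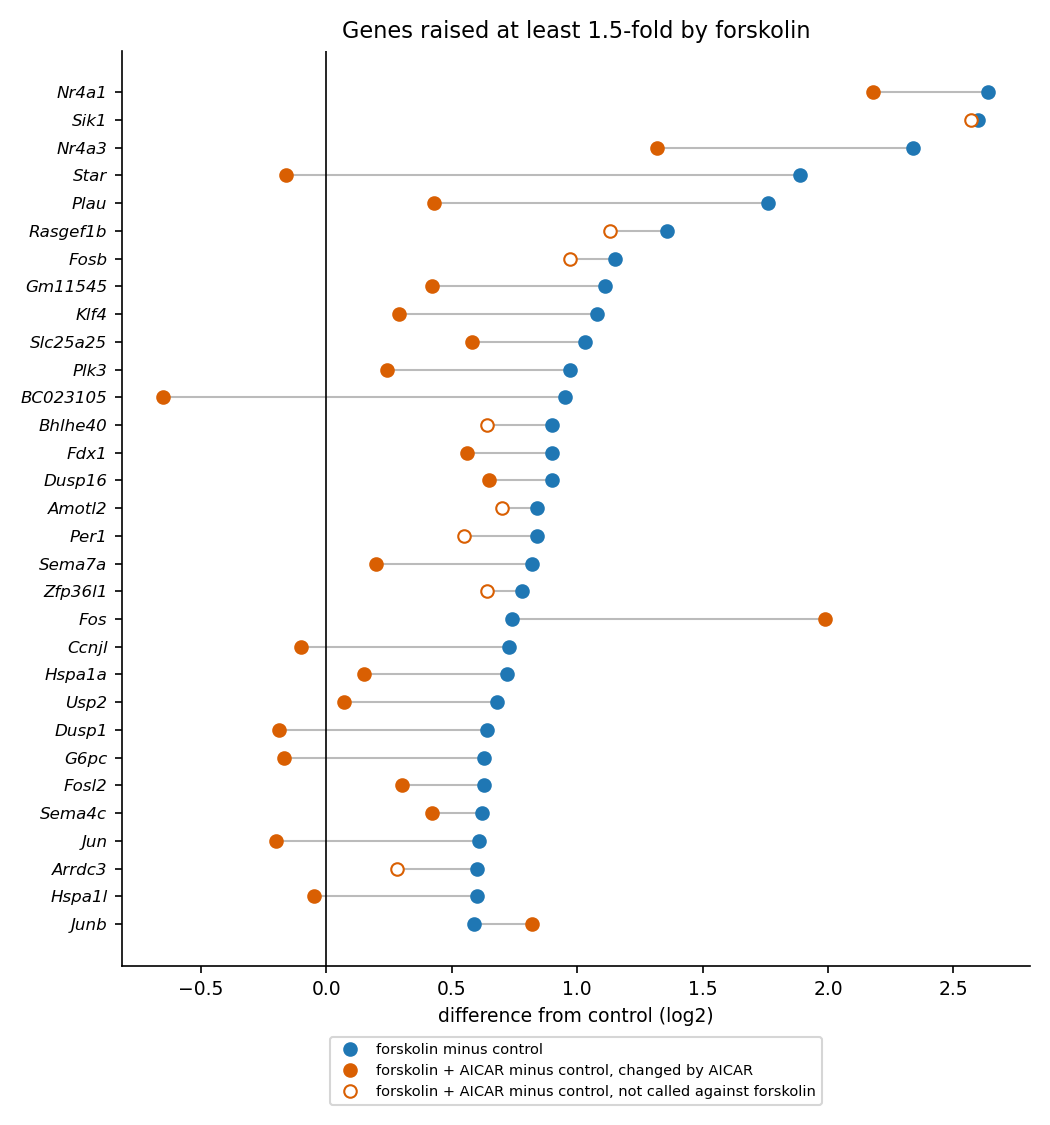
Log2 difference from control (horizontal axis) of the 31 genes that forskolin raised at least 1.5-fold, with forskolin alone (blue) and with forskolin and AICAR (orange, open where not called against forskolin). Sik1 stayed at 2.57 above control with both compounds, Star went from 1.89 to −0.16 and Fos from 0.74 to 1.99.

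Against control, limma called 18 of the 31 genes that forskolin raised at least 1.5-fold higher with both compounds, and the median log2 difference of the 31 was 0.42, against 0.84 with forskolin alone. The 31 were picked against the same control arrays, so chance values of these arrays enter both medians, and how much they add was not computed. Sik1 stood 5.96-fold above control (log2 difference 2.57, SE 0.07, adjusted p = 8.5e-08), Nr4a1 4.53-fold (2.18, SE 0.05), Fos 3.98-fold (1.99, SE 0.09) and Nr4a3 2.5-fold (1.32, SE 0.07). Rasgef1b (1.13), Fosb (0.97), Egr1 (0.90) and Junb (0.82) were also higher. Txnip was 2.47-fold below control (−1.30, SE 0.14), and Mir379, Gdpgp1, Mir127, Mir380, Zfp719, Zfp229 and Zfp418 were lower by log2 differences of −1.26, −1.20, −1.14, −1.12, −1.02, −1.01 and −0.94. Of 19938 genes, 1739 changed, 606 higher and 1133 lower (34.8% higher), and 137 at least 1.5-fold, 18 higher and 119 lower. Jun (−0.20, adjusted p = 0.1), Hsd3b1 (−0.37, adjusted p = 0.11), Cyp11a1 (−0.01, adjusted p = 0.94), Cyp17a1 (−0.05, adjusted p = 0.76), Nr5a1 (−0.10, adjusted p = 0.1), Nr0b1 (−0.09, adjusted p = 0.18) and Crem (0.06, adjusted p = 0.39) did not pass the test. The groups did not overlap in 29.5% of genes, against 10% by chance. The count was 4741 without AICAR replicate 1, where rises outnumbered falls (2675 and 2066), as they did with array weights (3578 and 3041). It was 682 without AICAR replicate 2, 660 without control replicate 3, 795 without control replicate 2, and 1030 to 1149 without control replicate 1, forskolin replicate 1 or 2, or AICAR replicate 3. With the array axis as a covariate it was 642, and without replicate 3 of every group 377.

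By list, 9 of 32 immediate early genes were higher than control and Ier2 and Klf10 lower (15 and 4 adjusted over the list alone), and 9 of 29 cAMP and CREB targets were higher and Cited2 and Inhba lower (13 and 3 adjusted over the list alone). Only Fdx1 (0.56, SE 0.05) of the 19 steroidogenesis genes was called higher, and none was called lower (1 and 0 adjusted over the list alone). Dusp16 (0.65), Dusp4 (0.39), Spry1 (0.31), Dusp5 and Dusp8 of the MAPK phosphatase and Sprouty list were higher and Errfi1 (−0.68) and Dusp7 lower (5 and 5 adjusted over the list alone). Among clock genes Bhlhe40 (0.64), Nfil3 (0.58), Per1 (0.55), Rora (0.17) and Csnk1e were higher (5 and 2 adjusted over the list alone). Among glycolysis and hypoxia genes Adm (0.45), Ankrd37 (0.44), Hk2 (0.36) and Vegfa (0.36) were higher and Pfkfb3 and Pfkfb4 lower (7 and 2 adjusted over the list alone). Smad7 (0.48) and Smad6 (0.41), inhibitors of TGF-beta and BMP signalling, were higher and Inhba (−0.56) and Tgif1 (−0.22) lower (2 and 2 adjusted over the list alone). The nuclear receptor gene Nr0b2 was lower (−0.84, SE 0.04), as were Sox9 (−0.56), Bcl6 (−0.65) and Ddit3 (−0.57). Of 20 AMPK components, the scaffold gene Fnip1 (0.32) was higher and Prkaa1 (−0.24), Prkag3 (−0.24) and Prkab1 (−0.20) lower (1 and 3 adjusted over the list alone). In the germ cell and endothelial lists limma called no member, with 6 of 28 genes at an unadjusted p under 0.05 and 0 adjusted over the list alone. Camera called 8 sets, higher for immediate early, cAMP target, glycolysis and peritubular lists and lower for cholesterol, purine, unfolded protein and cell cycle lists (adjusted p from 0.00078 to 0.046), but with an estimated correlation all 8 lost their call (adjusted p = 0.53, 0 lists at an unadjusted p under 0.05), and fry called 9 lists. The 4 calls of lower lists and that of the peritubular list ended after quantile normalization (adjusted p = 0.093 for the peritubular list), with the intensity trend removed (0.062) and with the array axis as a covariate (0.15). With 1 array left out, the cholesterol set lost its call in 6 cases (adjusted p up to 0.091, without AICAR replicate 2), the glycolysis set without AICAR replicate 1 (0.18) or control replicate 1 or 2, the unfolded protein set without AICAR replicate 2 (0.11) or control replicate 2, and the cell cycle set without AICAR replicate 3 (0.12) or control replicate 2. The uncalled p53, integrated stress and Sertoli sets had medians of 0.01, 0.02 and 0.02 but camera put them lower. Of the 65 called genes named for this comparison, 26 lost their call with at least 1 array left out. Among them were Mir380 without AICAR replicate 2 (adjusted p = 0.052), Dusp4 without control replicate 3 (0.053) and, without at least 1 of these arrays and without others, Zfp229 (up to 0.13), Spry1 (0.11), Rora (0.14), Tgif1 (0.11), Prkaa1 (0.087), Prkag3 (0.076) and Prkab1 (0.12). With the array axis as a covariate 22 lost it.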

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

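The array axis as a covariate, the removal of the intensity trend and the omission of replicate 3 of every group were chosen after the data were seen, as were the tests on them. Star kept its direction and its call in both of its called comparisons under every alternative run, as did 76 of the 171 named gene results past the threshold. Numbers of genes changed are given in the order forskolin against control (138), AICAR with forskolin against forskolin (1017) and both compounds against control (1739). With a replicate block they were 83, 583 and 874, of which 79, 571 and 856 were among those reported. Whether the replicate numbers pair the samples was not settled. Forskolin replicates 1 and 3 correlated best with the control of their own number (r across genes 0.24 and 0.33), and replicate 2 did not (0.01). No AICAR replicate correlated best with the forskolin replicate of its own number (−0.41, 0.08 and −0.34). The numbers of genes changed were 72, 544 and 735 without moderation and 436, 5729 and 6619 with array weights. They were 33, 144 and 141 at an unadjusted p under 0.05 with 1.5-fold, and 72, 409 and 502 at an adjusted p under 0.01. With the array axis they were 213, 658 and 642, and without replicate 3 of every group 43, 241 and 377. Fits of 2 groups gave 496 and 758 for the later comparisons. With 1 array left out they ranged from 76 to 144, 487 to 3324 and 660 to 4741. The 72 forskolin-induced genes lower with AICAR became 40 without moderation, 152 with array weights, 14 at an unadjusted p with 1.5-fold, 41 at an adjusted p under 0.01, 23 without replicate 3 of every group and 44 to 78 with 1 array left out. Stricter thresholds lower such counts by construction. Omitted arrays, fits of 2 groups, a replicate block and the axis covariate leave fewer degrees of freedom, and without moderation no spread is shared between genes. That by itself tends to make calls fewer, by an amount that was not separated. What else moved the counts was not tested. With array weights the split was 212 higher and 224 lower, 3075 higher and 2654 lower, and 3578 higher and 3041 lower, so the excess of rises with forskolin and of falls in the later comparisons was not kept. The median of −0.46 became −0.49 with quantile normalization, −0.52 with median centring, −0.54 with array weights, −0.51 with every probe, −0.43 with the intensity trend removed, −0.55 without replicate 3 of every group, −0.36 with no minimum fold and −0.54 to −0.43 with 1 array left out. Lists called numbered 11, 11 and 8. With an estimated correlation they were 3, 0 and 0 (5, 1 and 0 at an unadjusted p under 0.05), and fry called 7, 12 and 9. The array axis gave 6 and 3 in the later comparisons. For AICAR with forskolin against forskolin, quantile normalization and the intensity trend removed each gave 8, with 6 lower against the 9 reported. For the last comparison quantile normalization gave 4, a mean log2 value of at least 5 gave 5 and the intensity trend removed 3. The array axis, quantile normalization and the trend removed each ended its 4 calls of lower lists and that of the peritubular list. With 1 array left out they ranged from 9 to 12, 9 to 11 and 4 to 9. The called rise of Mir99ahg became −0.11 with the mean of probes, since its probes disagree. The other reversals were of uncalled genes near 0. Nr0b1 with forskolin was 0.00 without replicate 3 of every group and −0.07 to −0.02 with 1 array left out. Nr5a1 with AICAR was −0.00 with array weights, −0.01 with the array axis and without replicate 3 of every group, and −0.00 to 0.02 with 1 array left out. Against control, Cyp11a1 was 0.01 with quantile normalization, 0.05 with the array axis and without replicate 3 of every group, 0.02 with the trend removed and −0.04 to 0.02 with 1 array left out. Cyp17a1 was 0.13 with the array axis, 0.12 without replicate 3 of every group and −0.15 to 0.05 with 1 array left out, and Crem was −0.04 with quantile normalization and with the trend removed. What signal over background limits was tested only through the filters on the mean log2 value.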

Other observations

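The gene classes below were defined after the AICAR comparison was seen, and the tests of the array axis on the forskolin-induced genes and on changes picked by size alone, of the further simulations and of the intensity trend were chosen after their results were seen.

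Some of the microRNA genes that lie in the imprinted cluster between Meg3 and Mirg were lower with AICAR added. Of 40 measured there limma called 17 lower than with forskolin alone and 0 higher (28 and 0 at an unadjusted p under 0.05), with a median log2 difference of −0.36, against 12 lower and 5 higher of 260 microRNA genes elsewhere, with a median of 0.04. The 40 were brighter, at a median log2 level of 7.53 against 5.89 elsewhere, and no comparison matched on level was made. With the intensity trend removed the 2 medians were −0.36 and 0.00. Mir379, Mir380 and Mir127 fell furthest (−1.33, −1.26 and −1.25), and Mir379 was dim, with log2 values from 4.6 to 6.51. With the array axis as a covariate their changes were −0.95, −0.94 and −1.27. Genes of 1 cluster need not vary independently, so the 40 are not separate replicates. The long RNA Rian of the same cluster was also lower (−0.62, adjusted p = 0.00091), whereas Meg3 did not pass the test (−0.03, adjusted p = 0.75). Forskolin alone gave a median of 0.08 for the 40, and limma called none of them (1 at an unadjusted p under 0.05). The median with AICAR was −0.34 after quantile normalization and −0.27 with the array axis as a covariate, where 15 were lower. Whether these probes read the mature or the primary transcript is not given in the sources used here. Of 31 histone genes limma called 9 lower with AICAR and 0 higher (21 and 1 at an unadjusted p under 0.05), with a median of −0.18 (−0.10 and 5 lower with the array axis). Of 51 small nucleolar RNAs limma called 3 lower and 0 higher (21 and 2 at an unadjusted p under 0.05), with a median of −0.16, but with the axis 1 lower and 2 higher, with a median of −0.04. Of 49 ribosomal protein genes 1 was lower and 0 higher (1 and 3 at an unadjusted p under 0.05). Of 1027 olfactory receptor genes 7 were lower and 5 higher, but 16 lower and 118 higher at an unadjusted p under 0.05, with a median of 0.06 (0.01 with the axis).

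Genes raised by forskolin were lowered by AICAR, 72 in number and Star first among them. Of 100 groupings of the 9 arrays, only the real 1 gave as many, and the highest of the others gave 24. Groupings that mix treatments carry the treatment effects into the spread within groups, which lowers their counts. These counts therefore do not show what chance alone would give. With the array axis as a covariate 84.7% of the 72 (61 genes) were still in the count, but genes picked by their call have little room for the axis. All 99 genes raised by forskolin were picked without regard to their AICAR change, and its median was −0.36 without and −0.35 with the axis. The spread in their test included the AICAR arrays, however, so genes that follow the axis were less likely to be picked. These medians therefore do not decide whether the axis is the cause. Chance values of the shared forskolin arrays stay open for part of the count. Of 100 simulated data sets without effects, 99 gave 0 such genes but 1 gave 2585. Of 1000 further ones, added after that result, 3 gave at least 72 (highest 792). The simulated data held no forskolin effect either, so they do not decide how much of the 72 comes from the shared arrays. Where the forskolin array measured was not used to pick the genes, the median was still −0.38 to −0.58, which is consistent with AICAR opposing part of the forskolin response, a hypothesis found and tested on the same data.

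For the breadth of the AICAR response, other splits of the 6 arrays of each comparison are too few (10) for a share under 0.05: 1 of 10 splits, the real one, gave as many genes for forskolin against control (138, highest other 0), for AICAR (1017, highest other 0) and for both compounds against control (1739, highest other 0). At an unadjusted p under 0.05 limma gave up to 1213, 3252 and 3318 genes in the other splits and 1450, 4801 and 6199 in the real ones. The other splits mix treatments, which carries treatment effects into the spread within groups and lowers their counts. They therefore do not show what chance alone would give. Of all 1017, 88.5% (900) were called the same way with each array's intensity trend removed, which argues against that trend as the whole cause, but only 549 with the array axis as a covariate. For the 145 genes at least 1.5-fold apart, picked by size alone, a median of 90.7% of the change was left with the axis. Among them 132 were called, and 97% of these (128) were called the same way with the axis. Genes picked by their call have little room for the axis, so both shares were largely set by the calls. For the 13 not called a median of 45.8% was left, so the axis as the cause was not decided for the 145. Of the 885 changed less than 1.5-fold, 47.6% (421) kept their call with the axis, a share between the bounds set in advance for and against it, where changes were slightly smaller (a median of −0.31 and then −0.27 for the lower ones), errors slightly larger (median SE 0.054 and then 0.056) and the degrees of freedom 1 fewer; since genes picked by their call have little room for the axis, these medians decide nothing, the axis and an effect of AICAR cannot be told apart for these genes, and what the axis stands for was not tested.

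Zinc finger genes named Zfp with a number were lower with AICAR as a class. Of 317, 86 were lower and 3 higher, with a median of −0.16, and Zfp719 (−1.04), Zfp40 (−0.90) and Zfp455 (−0.88) fell furthest among those called; with forskolin alone limma called none (9 higher and 21 lower at an unadjusted p under 0.05) and the median was −0.01. Their expression level alone is argued against, since 0% of 10000 random lists matched on mean log2 value had a median as low (−0.02 to 0.04). Those lists do not keep the correlation between Zfp genes, and the class was defined after the comparison was seen, so this share does not measure chance. The array axis is argued against as the whole cause, since 67.4% of the median was left with it as a covariate (−0.11, 64 lower and 1 higher), and quantile normalization gave −0.13. An effect of AICAR on this class stays open as a hypothesis, and its mechanism was not tested.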
